A study of Xenopus laevis with 3 samples.

How the data were processed

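Spatial gene expression was measured in amputated tails of the African clawed frog Xenopus laevis on 3 Visium capture areas, glass fields of 4992 barcoded spots that capture polyadenylated RNA from the tissue lying on them. Tadpoles lost about 30% of the tail at stage 40, at which tails regenerate, or at stage 46, at which they are refractory and do not. Tails were collected 6 hours (6 hpa), 1 day (1 dpa) or 3 days (3 dpa) after amputation, embedded in cryostat medium, and sectioned sagittally at 20 µm. The first capture area held regenerating and refractory tails of 3 dpa, the second refractory tails of 6 hpa and 1 dpa, and the third regenerating tails of 6 hpa and 1 dpa. Age at amputation and regenerating class were therefore the same variable in every comparison, and at 6 hpa and 1 dpa the class was also the capture area.

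The deposited matrices hold raw UMI counts, distinct RNA molecules per gene and spot, for all 4992 spots of each capture area and without normalization. Per the file headers they were written by Cell Ranger 4 software, and the submitters' processing notes name Space Ranger, without a version, and Seurat 5. The genome build and gene annotation behind the counts were not given in the sources used here. A deposited table per capture area lists the spots that the authors kept, with UMI counts and detected gene counts per spot, the condition of each spot, and a mark for the spots that entered their deconvolution. The same tables by the authors give the mitochondrial share of each spot as a percent of its UMIs, which stayed under 20 percent in every listed spot. The authors' tables held 1795, 1216 and 2121 spots on the first, the second and the third capture area, 5132 in all, against 5195 spots placed under tissue by Space Ranger. UMI totals recomputed from the matrices equalled the authors' totals in every listed spot. Images, pixel positions and scale factors were not used here.

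The authors' tables name the condition of each spot but not the tail section. Spots of a condition were divided into tail sections by array position, to the number of replicates in the labels. K-means with 100 starts and connected pieces (spots within 2.1 array columns) were used. Any marked spots were divided apart, into 4 sections. This gave 40 tail sections, 8, 8 and 6 regenerating at 6 hpa, 1 dpa and 3 dpa and 6 refractory at each time, with 55 to 221 spots and 787648 to 2815795 UMIs each. The labels do not say whether the sections came from separate animals. If several came from 1 animal, the p-values measure the spread between sections only. Mean UMIs per section were 1669450, 2015870 and 1782100 in regenerating tails and 1476630, 1984580 and 1731080 in refractory tails at 6 hpa, 1 dpa and 3 dpa. Genes with low counts were given as CPM without a fold where a condition held 3 counts or fewer.

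UMIs were summed per gene and tail section, and the section was the replicate throughout. Of 44478 gene symbols, 44440 matched the reference gene table, and 38 did not, most of them mitochondrial. Genes are named by the symbols of the files, where .L and .S mark the gene copies on the long and short subgenomes. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, robust dispersion) in R 4.3.3, with all 40 sections and 1 coefficient per condition, over 15163 genes. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The 6 contrasts were regenerating against refractory tails at 3 dpa, 6 hpa and 1 dpa, 1 dpa against 6 hpa within each class, and the difference of those time changes between classes. An effect of the capture area that adds equally to both times cancels in the last of these. Fold changes are log2 values with the standard error (SE), CPM values are means with the standard deviation (SD) over sections.

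Named genes followed a fixed rule. Per comparison they were the 12 largest rises and 12 largest falls past the threshold with at least 20 CPM in the higher condition. Provisional symbols except XB symbols were left out, with 1 homeolog per gene. Per gene list they were the 2 members risen and the 2 fallen with the smallest adjusted p, or the 2 most abundant where none passed. The tests, the gene lists and this rule were chosen before the data were examined.

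The 26 gene lists were matrix metalloproteases, immediate early and AP-1 genes, cytokines and inflammatory signalling, myeloid and leukocyte markers, apical epidermal (regeneration organizing cell) markers, Wnt and FGF ligands and targets, BMP and TGF-beta ligands and targets, cell cycle, skeletal muscle, muscle progenitors and myogenic factors, notochord and cartilage, spinal cord and neurons, epidermis, goblet, ionocyte and ciliated epidermal cells, connective tissue and fibrous matrix, blood, endothelium, pigment cells and neural crest, gut, liver and pancreas, hypoxia and glycolysis, heat shock and unfolded protein, oxidative stress, p53 targets and apoptosis, posterior Hox and caudal genes, ribosomal proteins, and nuclear oxidative phosphorylation genes. Each homeolog counted as 1 member. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over 150 tests, and again with an estimated correlation and with fry. Counts of members past the threshold are given with adjustment over all genes and adjusted over the list alone.

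Spots were grouped into 8 regions by Leiden clustering (resolution 0.35, seed 1) on 15 nearest neighbours in 20 principal components of 1610 variable genes, with capture areas centred separately, in Python 3.11.15 with scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2. Conditions were compared inside a region over sections with at least 5 spots in it. Shares of spots per region were compared by exact permutation tests, two-sided, only for regions whose leading genes did not differ between the conditions. Co-localisation was the Spearman correlation, across spots of a section, between the UMI shares of 2 gene lists, tested over sections by an exact sign-flip permutation, two-sided, in sections with at least 30 spots. Other computations used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and data.table version 1.17.8, and figures used matplotlib 3.10.9.

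The tests were tested on simulated data. Counts were drawn for the 40 sections from 1 mean profile, the measured dispersions and the real section totals, and 200 genes were changed in 1 condition. At 1.5-fold, 2-fold and 4-fold changes edgeR recovered 16.4%, 65.7% and 93.9% of changed genes in the 3 dpa design and 38.8%, 82.1% and 97.0% in the 6 hpa design. The 1 dpa design gave 28.4%, 74.6% and 95.5%. For 1 dpa against 6 hpa, recovery was 43.3%, 77.6% and 100% in the regenerating design and 20.9%, 82.1% and 93.9% in the refractory design. The difference of the time changes recovered 2.99%, 40.3% and 86.4%.

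The alternatives were DESeq2 1.42.0, limma-voom, library totals without TMM, no filter on low counts, a fit with only the conditions compared, all spots under tissue, spots with at least 500 UMIs, sections thinned to the smallest total, homeologs summed, ribosomal, mitochondrial and haemoglobin genes left out, regions weighted equally (pseudocount 1), and each section left out in turn. Added after seeing the data were the sections marked by the authors alone (20 sections, none of them refractory at 6 hpa), touching pieces counted as 1 section, subtraction of the RNA profile of spots outside tissue, list counts under every alternative, and a test of co-localisation between classes. Reads and the authors' deconvolution results were not analysed.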

Results

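The series measured where genes were expressed in amputated tadpole tails that regenerate and in older tails that do not, with the stated aim of characterising cells that start regeneration. The first capture area, with 6 regenerating and 6 refractory sections at 3 dpa, held 32930468 UMIs. The second held 35178349 UMIs and 6 refractory sections each at 6 hpa and 1 dpa, and the third held 50408942 UMIs and 8 regenerating sections each at 6 hpa and 1 dpa. Median UMIs per listed spot were 9197, 13221.5 and 12642 on the first, the second and the third capture area. Spots outside tissue also held UMIs, 35.4%, 38.0% and 41.5% of each capture area's total. Correlations of log2 CPM between sections of a condition ranged from 0.805 to 0.964. The spots fell into 8 regions by expression, drawn on the map of sections.

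**Figure D1:**
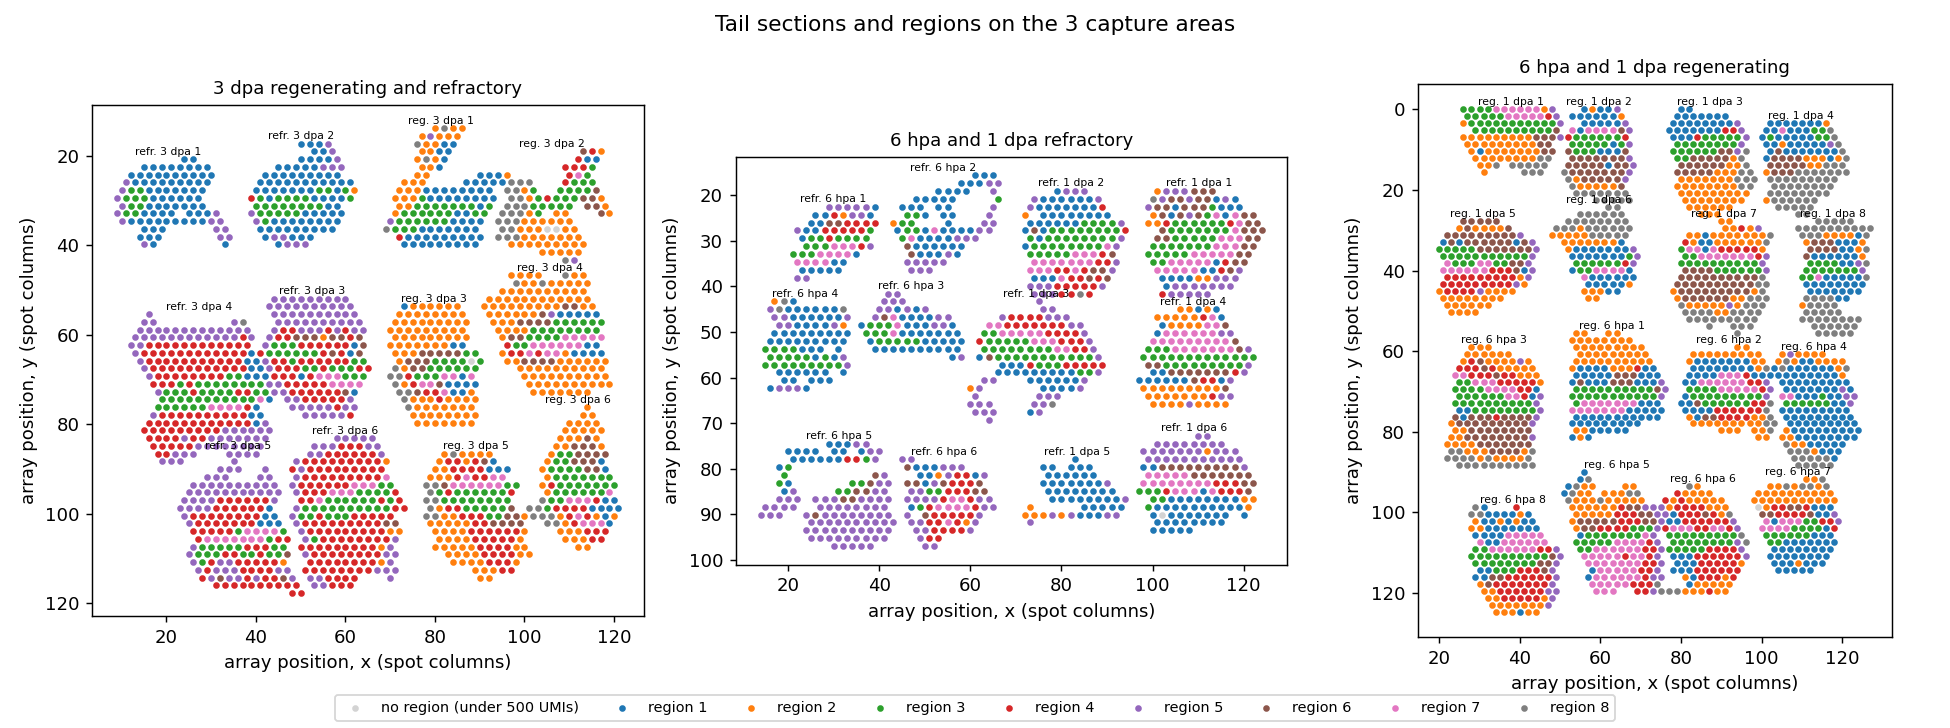
Each point is a spot of the authors' tables at its array position (both axes in spot columns), with 1 panel per capture area and colours for the 8 regions. The 40 tail sections are labelled by class, time and number, and the 3 dpa classes share 1 capture area.

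Regenerating and refractory tails at 3 dpa were compared on 1 capture area, which addresses what separates tails that can regrow from tails that cannot without a difference in capture area. Regenerating tails had more transcripts of the epidermal keratin krt12.4.S (203 ± 123 against 28.4 ± 9.21 CPM, SD, n = 6 and 6) and of the secreted lectin itln1.L (1210 ± 601 against 204 ± 82.7 CPM, n = 6 and 6). Refractory tails had more thdl17.L (526 ± 211 against 14.4 ± 2.81 CPM, n = 6 and 6), more of the mucin muc1.S (73.9 ± 26.6 CPM in refractory tails, log2 -2.61) and more of the contractile genes tagln.L and acta2.L. As lists, immediate early genes (20 of 44 members past the threshold) and ribosomal protein genes (44 of 131) were lower in regenerating tails and apical epidermal markers (4 of 20) higher at the preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.206, 0.445 and 0.358), and the ribosomal count ran from 7 to 107 without single sections. Of 15163 genes, 345 were higher and 509 lower in regenerating tails, 165 and 256 of them by more than 2-fold.

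The 12 largest rises began with ocm4.7.L (log2 2.86 ± 0.72 SE, adjusted p = 0.0150), krt12.4.S (2.81 ± 0.50, adjusted p = 0.000762), itln1.L (2.57 ± 0.55, adjusted p = 0.00414), cat2.L (2.38) and akr1c2.L (2.28 ± 0.41, adjusted p = 0.000815). They were followed by cpa6.L (2.17), ocm4.6.S (2.00), tll2l.L (1.96), slc26a4.3.S (1.89), XB5774338.L (1.87), otos.S (1.82) and tmprss2.2.L (1.73). The ocm4 genes encode oncomodulin-like calcium binding proteins. The 12 largest falls began with thdl17.L (-5.18 ± 0.54, adjusted p = 7.48e-08), the BMP antagonist chrdl1.L (-4.66), the myosin light chain myl4.L (-4.40), cytl1.L (-3.74) and the myosin heavy chain myh13.S (-3.61). Next were ampd3.L (-2.88), the collagenase mmp13l.L (-2.86), the muscle atrophy gene fbxo32.S (-2.70), muc1.S (-2.61 ± 0.32, adjusted p = 1.51e-06), tagln.L (-2.57), lbhd1.S (-2.40) and acta2.L (-2.39 ± 0.54, adjusted p = 0.00653). The ranges of thdl17.L, krt12.4.S and itln1.L did not overlap between the classes.

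The call was kept without each section and in every alternative for krt12.4.S, akr1c2.L, cpa6.L, tmprss2.2.L, thdl17.L, ampd3.L, muc1.S, tagln.L and lbhd1.S. A single section ended it for 8 genes. ocm4.7.L lost it without regenerating section 1 (adjusted p = 0.108, range 0.000648 to 0.128 over its alternatives), a section with 642 CPM. chrdl1.L (adjusted p = 0.0683) and cytl1.L (0.220) lost it without refractory section 1, and myl4.L without refractory section 1 or 2 or regenerating section 5 (up to 0.0887). myh13.S lost it without refractory section 1 or 2 or regenerating section 2, 3, 4, 5 or 6 (up to 0.220), and XB5774338.L without refractory section 1, 3, 4 or 5 or regenerating section 3 or 5 (up to 0.0791). ocm4.6.S held only without regenerating section 2 or 6 (otherwise up to 0.333). tll2l.L lost it without refractory section 1, 2, 3, 5 or 6 or regenerating section 2, 3 or 5 (up to 0.162). Other alternatives ended it for itln1.L with touching pieces as 1 section (0.0539, range 0.000144 to 0.0539) and for cat2.L, slc26a4.3.S, otos.S, mmp13l.L, fbxo32.S and acta2.L in 2 to 6 alternatives each.

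**Figure D2:**
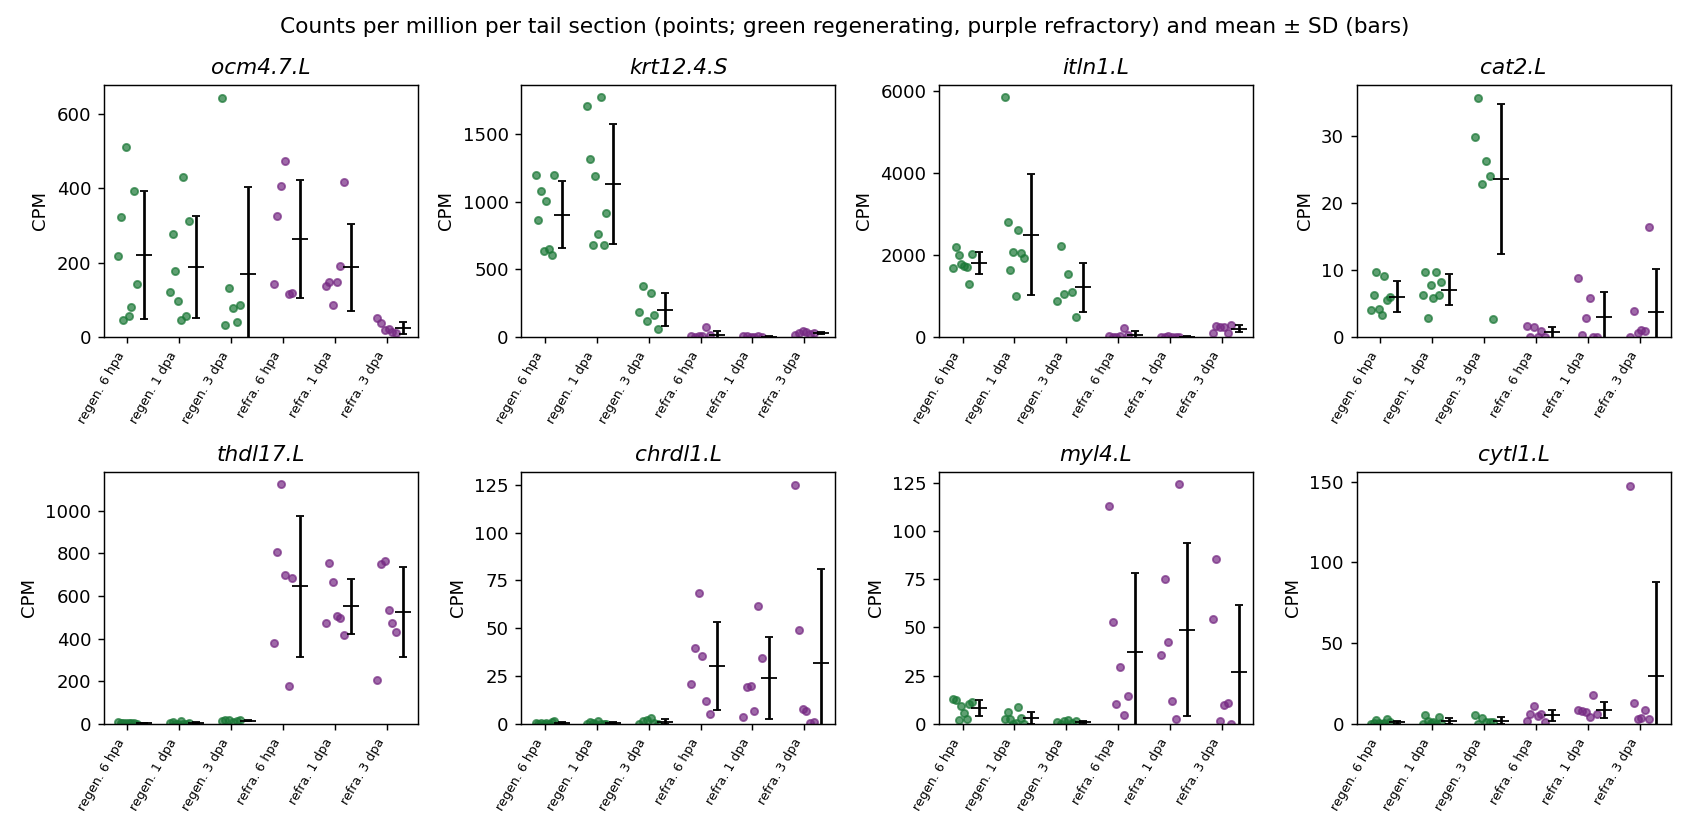
Each panel shows 1 gene with CPM on the vertical axis (from 0) for every tail section (points) in the 6 conditions, with mean and SD. The mean of thdl17.L was 526 CPM in refractory and 14.4 CPM in regenerating tails at 3 dpa, and krt12.4.S and itln1.L were higher in regenerating tails at each time.

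Gene lists were then compared at 3 dpa. Immediate early and AP-1 genes, which injury switches on within minutes, were lower for 20 of 44 members and higher for 0 (27 lower adjusted over the list alone), among them gadd45g.L (-1.31) and dusp1.L (-1.36). The list's camera test gave adjusted p = 1.49e-17, and adjusted p = 0.206 with an estimated correlation. Ribosomal protein genes were lower for 44 of 131 members (108 adjusted over the list alone), with rpl35a.S at -1.70 and rps16.L at -0.64 (adjusted p = 3.77e-31, and 0.445 with an estimated correlation). Cytokines and inflammatory signalling genes were lower for 6 of 26 (6 alone), including the neutrophil attractant cxcl8.S (-2.37) and the receptor cxcr4.S (-0.99) (adjusted p = 0.00971, and 0.253 with an estimated correlation). Apical epidermal markers were higher for 4 of 20 (7 higher and 1 lower alone), with cpa6.L and dlx3.S (1.67) (adjusted p = 1.76e-06, and 0.358 with an estimated correlation). BMP and TGF-beta genes were higher for 6 and lower for 1 of 34 (14 and 2 alone), with id3.L at 0.92 and pmepa1.S at -1.09 (adjusted p = 2.62e-07, and 0.247 with an estimated correlation). Connective tissue genes were higher for 5 of 50 (9 and 2 alone), with sparc.L at 0.68 and twist1.L at 0.63 (adjusted p = 5.16e-06, and 0.335 with an estimated correlation). Cell cycle genes were higher for 2 of 55 (2 alone), tpx2.S (0.88) and hmgb2.L (0.45) (adjusted p = 2.86e-05, and 0.458 with an estimated correlation). Notochord and cartilage genes were higher for 4 and lower for 1 of 24 (7 and 1 alone), with col11a1.S at 0.83, not.L at 1.84 and acan.L at -1.85 (adjusted p = 5.58e-05, and 0.445 with an estimated correlation).

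Smaller shifts passed camera for 5 other lists. Posterior Hox genes were higher for 2 of 23 (6 and 1 alone), hoxd10.S (0.91) and hoxa9.L (0.70), with adjusted p = 0.0118, and 0.456 with an estimated correlation. Endothelial genes were higher for 1 of 17 (1 alone), egfl7.S (1.13), with adjusted p = 0.0197, and 0.783 with an estimated correlation. Hypoxia and glycolysis genes were higher for 2 and lower for 2 of 34 (3 and 7 alone), with p4ha1.L at 0.73 and bnip3.L at -1.78 (adjusted p = 0.00896, and 0.445 with an estimated correlation). Oxidative stress genes were lower for 3 of 28 (7 alone), with sqstm1.L at -0.63 (adjusted p = 0.00237, and 0.335 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower for 1 of 132 (1 alone), cox4i2.S (-0.88), with adjusted p = 3.93e-05, and 0.860 with an estimated correlation. The other lists did not pass with TMM. Matrix metalloproteases were lower for 3 of 17 (5 alone), with mmp13l.L and mmp8.S (-2.29) (adjusted p = 0.0662), and myeloid markers for 2 of 25 (1 higher and 4 lower alone), c1qc.L (-2.15) and c1qb.L (-1.72). Epidermis was split, 4 higher and 2 lower of 31, with krt70.L at 3.59 and krt17.S at -4.26. Goblet and ciliated cell genes were higher for 2 of 15, itln1.L and tekt2.L (2.71). Spinal cord genes were lower for 2 of 38 (nes.L -1.52), muscle genes for 2 of 40, and p53 targets for 2 of 18 (btg2.S -1.04), where the median was 0.03 and the mean -0.08. Heat shock genes were higher for 2 and lower for 1 of 31 (serpinh1.S 1.15, hsp90ab1.S -0.40). No member passed among Wnt and FGF genes (sfrp2.L -0.66), muscle progenitors, blood, pigment cells (pmel.L -0.99) or the 2 gut genes (apoc1.L 0.73), too few for camera.

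Several 3 dpa counts depended on scaling or on 1 section. With library totals in place of TMM the median of all genes shifted by 0.18 log2, and 68.2% of called genes were higher in regenerating tails in place of 40.4% (580 higher and 270 lower). Regions weighted equally, also without TMM, gave 544 higher and 238 lower. Touching pieces as 1 section gave 113 and 172, and the outside profile subtracted 68 and 86. The count of lower genes was 336 without refractory section 1, 334 without regenerating section 3 or 4, 314 without regenerating section 5 and 307 without regenerating section 6. The 44 lower ribosomal genes became 7, 9, 29 and 71 without refractory section 1, 2, 4 or 6, and 107, 20, 12, 12, 15 and 11 without regenerating section 1, 2, 3, 4, 5 or 6, and 25 without the filter, 2 with only these conditions in the fit, 22 with homeologs summed, 18 with touching pieces and 5 with the outside profile subtracted. The 20 lower immediate early genes became 12 and 9 without refractory section 3 or 4, 12, 13, 9 and 12 without regenerating section 3, 4, 5 or 6, and 9 with library totals, 9 thinned, 12 with homeologs summed, 3 with regions weighted equally, 2 with touching pieces and 3 with the outside profile subtracted. The 6 lower cytokine genes became 3, 3 and 1 without refractory section 1, 3 or 4, 2, 3, 2 and 2 without regenerating section 3, 4, 5 or 6, and 1 with library totals. The 4 higher apical genes became 2 without refractory section 1, 2 or 5 or regenerating section 2, 7 with regions weighted equally and 1 with the outside profile subtracted. The 5 higher connective tissue genes became 2 and 3 without refractory section 1 or 2, 3 and 2 without regenerating section 4 or 5, 18 with library totals, and 0 with touching pieces or the outside profile subtracted. The 6 higher BMP genes became 3 without refractory section 1 and 10 with regions weighted equally, and the 4 higher notochord genes 8 with regions weighted equally. Without single sections the lower genes ran from 1 to 5 for oxidative stress, 1 to 6 for hypoxia (1 to 2 higher), 0 to 3 for p53 targets, 1 to 4 for myeloid and for muscle genes, 1 to 3 for oxidative phosphorylation and 1 to 2 for spinal cord, and the higher genes from 1 to 3 for Hox and 0 to 1 for endothelium. With library totals camera no longer passed for Hox (adjusted p = 0.0576) and endothelial genes (0.121), and passed downward for metalloproteases (0.0321), myeloid (0.0268), muscle (0.0323), spinal cord (0.0307) and pigment genes (0.0110). The muscle median turned upward, to as much as 0.50, without single sections.

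Regenerating and refractory tails at 6 hpa were compared to ask what differs by then, with no uncut tails. Class, stage and capture area coincided, so every 6 hpa value is also a difference between capture areas. Regenerating tails had higher mitotic genes, with plk1.S at 38.7 ± 4.43 against 3.36 ± 1.37 CPM and kif11.L at 28.2 ± 5.07 against 1.99 ± 0.901 CPM (SD, n = 8 and 6). Immediate early genes were lower in regenerating tails for 39 of 44 members, hypoxia and glycolysis genes for 23 of 34 and cytokines for 12 of 26, and the hypoxia and cytokine lists did not pass with an estimated correlation (adjusted p = 0.253 and 0.160). Refractory tails had more ptgs2.L, the inducible enzyme of prostaglandin synthesis (log2 -4.24), and cxcl8.S (-4.99). The retinoic acid degrading enzyme cyp26a1.S was at 51.6 ± 34.5 CPM in regenerating and 0.427 ± 0.474 CPM in refractory tails. Between capture areas, 3140 genes were higher and 3493 lower in regenerating tails, 1595 and 1795 by more than 2-fold.

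After cyp26a1.S, the largest rises between capture areas at 6 hpa were hbg2.L (6.01 ± 1.49, adjusted p = 0.00127), krt12.4.S (5.58 ± 0.55, adjusted p = 3.33e-10), ppp1r3c.2.S (5.13), itln1.L (5.03 ± 0.61, adjusted p = 2.36e-08), frem3.L (4.62), gfus.L (4.37) and fucolectin.S (4.11). Below these lay g6pc1.3.S (3.87), kif11.L (3.82 ± 0.30, adjusted p = 8.78e-13), htr3a.L (3.78) and plk1.S (3.52 ± 0.25, adjusted p = 9.65e-14). The largest falls were thdl17.L (-7.85 ± 0.56, adjusted p = 2.57e-13), the larval tail skin gene ouro1.S (0.231 against 64.5 CPM), cnfn.1.S (-6.94), the myelin gene mpz.S (-6.52), muc1.S (-6.49 ± 0.33, adjusted p = 1.46e-17, 3.78 ± 1.38 against 347 ± 116 CPM) and the muscle gene tcap.S (-6.34). They also included ouro2.L (-6.19), chrdl1.L (-5.92), the growth factor areg.L (-5.65), lrrn4cl.S (-5.62), ankrd2.S (-5.30) and the mitochondrial carrier slc25a4.L (-5.08). All 24 passed without each section. Subtraction of the RNA profile outside tissue ended the call for hbg2.L (adjusted p = 0.177, range 9.24e-07 to 0.177, also lost with limma-voom), krt12.4.S (0.101, range 7.22e-32 to 0.101), and itln1.L (0.938, range 6.14e-23 to 0.938). It also ended that of gfus.L (0.282, range 1.35e-19 to 0.282), fucolectin.S (0.765, range 2.39e-24 to 0.765) and htr3a.L (0.107, range 9.9e-12 to 0.107).

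Among the 6 hpa lists, again between capture areas, cell cycle genes were higher for 53 of 55 members (53 adjusted over the list alone) and lower for 0, with tpx2.S at 2.97 and cdk1.S at 2.84. This passed with the preset (adjusted p = 2.93e-40) and with an estimated correlation (0.0168). Immediate early and AP-1 genes were lower for 39 of 44 (39 alone), with dusp1.S at -3.06 and myc.L at -1.88, and also passed both ways (adjusted p = 9.28e-32 and 0.0401). Hypoxia and glycolysis genes were lower for 23 and higher for 4 of 34 (23 and 5 alone), with the glucose transporter slc2a1.L at -3.77, ddit4.L at -2.59 and p4ha1.S at 1.32 (adjusted p = 2.86e-05, and 0.253 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower for 99 and higher for 2 of 132 (111 and 2 alone), with cycs.L at -1.25 (adjusted p = 4.03e-09, and 0.790 with an estimated correlation). Cytokines were lower for 12 and higher for 1 of 26 (12 and 1 alone, adjusted p = 0.00118, and 0.160 with an estimated correlation), where lep.S was the higher member (1.67). Heat shock genes were lower for 20 and higher for 6 of 31 (20 and 6 alone), with dnaja1.L at -1.26 and pdia4.L at 1.15 (adjusted p = 0.00605, and 0.305 with an estimated correlation). Muscle genes were lower for 17 of 40 (17 alone), with tpm2.L at -2.04 (adjusted p = 0.000226, and 0.783 with an estimated correlation). Hox genes were higher for 13 and lower for 3 of 23 (14 and 3 alone), with hoxd9.S at 2.17, hoxa9.S at 1.75 and hoxc12.L at -0.98 (adjusted p = 0.000312, and 0.305 with an estimated correlation). Endothelial genes were higher for 9 of 17 (10 alone), with egfl7.L at 2.17 and tie1.L at 1.92 (adjusted p = 0.0369, and 0.790 with an estimated correlation).

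The other 6 hpa lists did not pass camera between capture areas. Apical epidermal markers were higher for 4 and lower for 1 of 20 (lef1.S 1.36, cpa6.L 2.93, tp63.L -0.73). Metalloproteases were higher for 4 and lower for 4 of 17, with mmp11.L at 3.08, mmp3.L at 2.29, mmp8.S at -4.04 and mmp1.S at -2.48, a median of 0.09 and a mean of -0.16. Wnt and FGF genes went both ways, 5 higher and 6 lower of 23 (fzd10.S 2.21, dusp6.L -1.52), with a median of -0.04 and a mean of 0.10. BMP and TGF-beta genes were higher for 12 and lower for 7 of 34 (tgfbi.L 1.24, ltbp1.S -1.86), connective tissue genes for 12 and 9 of 50 (postn.S 1.88, col3a1.L -0.99), and pigment genes for 7 and 0 of 15 (snai2.L 1.39). Muscle progenitor genes were lower for 4 of 13 (pax7.L -1.88, myod1.S -2.15). Myeloid markers were higher for 1 and lower for 3 of 25 (mpo.S 1.38, c1qc.L -4.12), and notochord genes for 5 and 1 of 24 (nog.L 1.93, col11a1.L -1.65). Spinal cord genes split 6 and 6 of 38 (zic1.S 1.66, nes.S -1.30), epidermal genes 6 and 10 of 31 (krt12.4.L 2.80, cldn4.S -2.68), goblet and ciliated genes 6 and 1 of 15, and blood genes 4 and 1 of 11 (rhag.L 3.03, tfrc.L -1.37). Oxidative stress genes split 7 and 9 of 28 (prdx1.S 1.17, sqstm1.L -1.64), p53 targets 6 and 6 of 18 (rrm2b.S 3.11, btg2.S -2.42) with a median of -0.03 against an upward test. Ribosomal genes split 18 and 13 of 131 (rpl35a.S higher, rpl23a.S -0.95), and 1 of 2 gut genes, too few for camera, was lower (a2m.S -1.89).

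With library totals the median of all genes at 6 hpa shifted by 0.22, and 63.5% of called genes were higher in place of 47.3% (4104 higher and 2354 lower), and 88 ribosomal genes were higher and 7 lower. Camera then passed for ribosomal genes (adjusted p = 3.10e-05) and no longer for endothelium (0.0876). Regions weighted equally, also without TMM, gave 2165 genes lower and 83 ribosomal genes higher. With the outside profile subtracted, 1095 genes were higher and 1770 lower. This left 34 cell cycle genes higher and 12 hypoxia, 64 oxidative phosphorylation and 4 muscle genes lower, and 2 endothelial and 0 apical genes higher. The split of ribosomal genes became 11 and 15 without refractory section 1, 17 and 8 without refractory section 3, 10 and 13 without refractory section 6, 10 and 15 without regenerating section 4, and 28 and 10 without regenerating section 5. The 99 lower oxidative phosphorylation genes became 54 without refractory section 3, the 4 higher apical genes 9 without refractory section 5, and the 6 higher spinal cord genes 10 without refractory section 1. With homeologs summed lep.S turned to -0.78, mpo.S to -0.50 and ndufa7.S to -0.30.

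Regenerating and refractory tails at 1 dpa were compared to ask what differs after the first day, and again each value is also a difference between capture areas. Regenerating tails had the keratin krt12.4.S at 1130 ± 443 against 3.03 ± 1.61 CPM and itln1.L at 2492 ± 1464 against 9.80 ± 3.14 CPM (SD, n = 8 and 6). Of apical epidermal markers 15 of 20 were higher in regenerating tails, with the transcription factor sp9.L at log2 4.54 and cpa6.L at 3.37. Of cell cycle genes 49 of 55 were higher, while 39 of 44 immediate early and 26 of 34 hypoxia genes were lower. With an estimated correlation the cell cycle list passed (adjusted p = 0.0347) and the apical (0.445), immediate early and hypoxia lists (0.0670 each) did not. Between capture areas, 3237 genes were higher and 3528 lower, 1608 and 1713 by more than 2-fold.

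At 1 dpa atp13a-like.S was at 28.2 ± 22.3 CPM in regenerating tails and had 0 counts in the 6 refractory sections, which allows up to 0.252 CPM (3 counts over the group), so it was at least 112-fold higher. Next came krt12.4.S (8.49 ± 0.66, adjusted p = 1.40e-12), itln1.L (7.96 ± 0.71, adjusted p = 3.52e-11), cyp26a1.S (7.35), tll2l.L (7.08) and ppp1r3c.2.S (6.12). Smaller rises were tmprss2.14.S (6.08), aifm3.L (5.41), gfus.L (5.39), fucolectin.S (5.39), the transcription factor bhlha9.S (5.33) and XB5774338.L (5.06). Lower between the capture areas were thdl17.L (-7.60 ± 0.55, adjusted p = 2.87e-13), tcap.S (0.197 against 35.6 CPM), cnfn.1.S (-7.05), ouro2.L (0.155 against 21.2 CPM), ouro1.S (-6.21) and mpz.S (-6.11). So were chrdl1.L (-5.72), ankrd2.S (-5.55), the myosin genes myl2.S (-5.50) and myh13.S (-5.39), slc25a4.L (-5.20) and lrrn4cl.S (-5.09). All 24 passed without each section. The call of ankrd2.S ended with limma-voom (adjusted p = 0.108, range 2.01e-05 to 0.108) and that of myh13.S with the outside profile subtracted (0.0858, range 8.4e-09 to 0.0858).

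Cell cycle genes at 1 dpa were higher between capture areas for 49 of 55 members (50 adjusted over the list alone), with plk1.S at 3.02 and ube2c.S at 2.95 (adjusted p = 3.46e-30, and 0.0347 with an estimated correlation). Immediate early and AP-1 genes were lower for 39 and higher for 2 of 44 (40 and 2 alone), with dusp1.L at -3.21 and btg1.L at 0.54 (adjusted p = 4.08e-26, and 0.0670 with an estimated correlation). Hypoxia and glycolysis genes were lower for 26 and higher for 3 of 34 (26 and 4 alone), with ddit4.L at -3.29 and slc2a1.L at -3.50 (adjusted p = 5.23e-09, and 0.0670 with an estimated correlation). Apical markers were higher for 15 of 20 (16 alone, adjusted p = 2.89e-05, and 0.445 with an estimated correlation). Epidermal genes were higher for 16 and lower for 3 of 31 (17 and 3 alone), with krt12.4.L at 4.15 and krt17.S at -1.67 (adjusted p = 0.000548, and 0.580 with an estimated correlation), and goblet and ciliated genes for 7 and 1 of 15 (7 and 1 alone, tekt2.S 1.71, adjusted p = 0.0202, and 0.445 with an estimated correlation). BMP and TGF-beta genes were higher for 18 and lower for 7 of 34 (19 and 7 alone), with the BMP targets id2.L at 1.35 and id3.L at 1.18 (adjusted p = 0.00605, and 0.542 with an estimated correlation). Muscle genes were lower for 19 of 40 (21 alone, adjusted p = 8.75e-05, and 0.757 with an estimated correlation). Hox genes were higher for 13 and lower for 3 of 23 (14 and 3 alone), with hoxa9.S at 1.93 and hoxc13.L at -0.82 (adjusted p = 0.000675, and 0.324 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower for 85 and higher for 2 of 132 (93 and 2 alone), with cox4i2.S at -1.07 (adjusted p = 1.77e-06, and 0.827 with an estimated correlation).

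**Figure D3:**
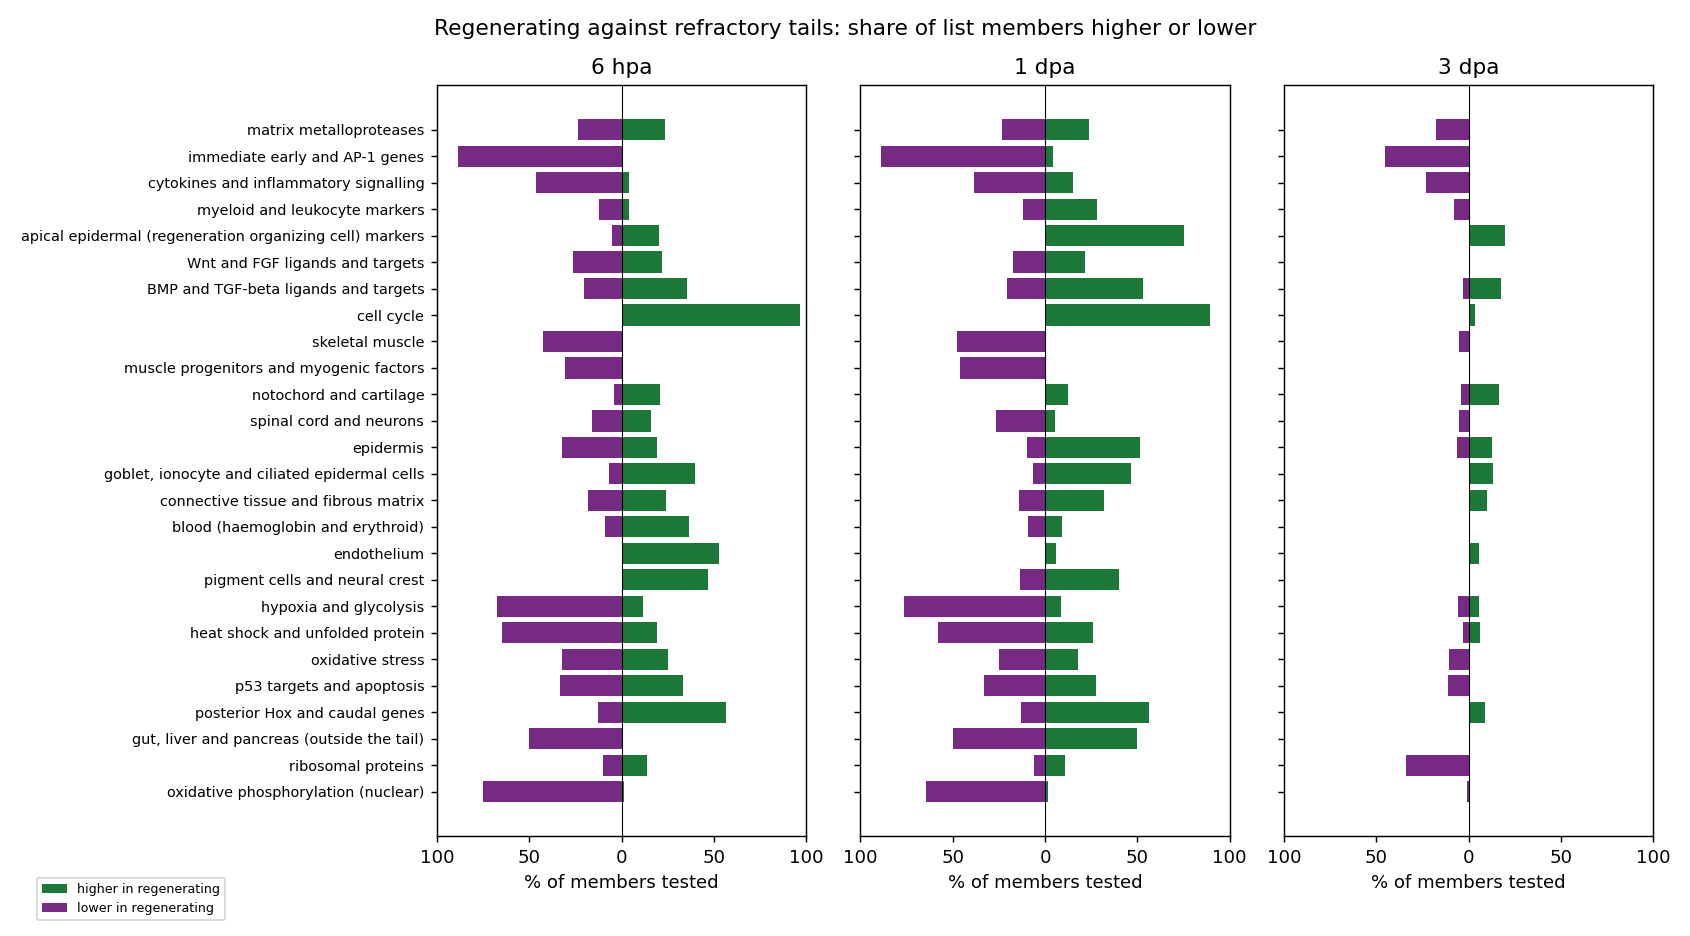
Bars give the percent of tested members of each gene list higher (green) and lower (purple) in regenerating than in refractory tails, with 1 panel each for 6 hpa, 1 dpa and 3 dpa. Cell cycle genes were higher for 53 of 55 members at 6 hpa and 49 at 1 dpa, both between capture areas, and 2 at 3 dpa on 1 capture area.

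The other 1 dpa lists did not pass between capture areas. Metalloproteases again split 4 higher and 4 lower of 17 (mmp3.L 3.40, mmp11.L 2.28, mmp8.S -3.25, mmp1.S -1.93), and cytokines 4 and 10 of 26 (tnf.S 2.58, ptgs2.L -3.99). Myeloid markers were higher for 7 and lower for 3 of 25 (mpo.S 2.90, c1qc.L -4.52), and connective tissue genes for 16 and 7 of 50 (postn.S 1.91, col3a1.L -0.92). Spinal cord genes were lower for 10 and higher for 2 of 38 (syt1.L 1.22), and muscle progenitors lower for 6 of 13 (pax7.L -2.05). Notochord genes were higher for 3 of 24 (matn4.S 1.81), with a median of -0.10 and a mean of 0.22, and Wnt and FGF genes split 5 and 4 of 23 (fzd10.S 2.52, dusp6.L -1.06), with a median of -0.15 and a mean of 0.18. Heat shock genes split 8 and 18 of 31 (calr.L higher, hspd1.S -1.27), oxidative stress genes 5 and 7 of 28 (prdx1.S 1.25, sod2.S -1.77) with a median of -0.24 against an upward test. The p53 targets split 5 and 6 of 18 (rrm2b.S 2.48) with a median of -0.09 against an upward test. Pigment genes split 6 and 2 of 15 (snai2.L 1.67, foxd3.S -1.74), ribosomal genes 14 and 8 of 131 (rpl35a.S 2.31, rpl38.L -0.82), blood genes 1 and 1 of 11 (hbg2.L 2.63) and gut genes, too few for camera, 1 and 1 of 2 (apoc1.L 2.50, a2m.S -2.15). 1 endothelial gene of 17 was higher (egfl7.L 0.95). The 14 higher ribosomal genes became 9 without refractory section 3, 62 with library totals and 75 with the sections marked by the authors, which also left 29 of the 85 lower oxidative phosphorylation genes. The 6 lower muscle progenitor genes became 3 and the 4 higher cytokine genes 2 without refractory section 5, and the 7 lower BMP genes became 4 without refractory section 4. With the outside profile subtracted, 814 genes were higher and 816 lower. This left 27 cell cycle, 7 apical, 5 epidermal, 1 goblet, 9 BMP and 8 Hox genes higher and 17 hypoxia, 14 oxidative phosphorylation and 6 muscle genes lower. Regions weighted equally, also without TMM, gave 2241 genes lower. With homeologs summed matn4.S turned to -0.49 and col3a1.L to 0.05.

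The class differences at the first times were compared with those at 3 dpa, since no section is shared between them. Genes higher at both 6 hpa and 1 dpa numbered 2087 and genes lower at both 2450, with 25 in opposite directions. Both of these comparisons set the same capture areas against each other, so an effect of the area alone would also give such agreement and a high correlation. Of these, 198 were also higher and 216 also lower at 3 dpa, on 1 capture area. Between 6 hpa and 3 dpa, 222 genes were higher at both times (71.4 by chance), 251 lower at both (117) and 67 opposite. Across genes, which are not independent replicates, the fold changes correlated with r = 0.81 between 6 hpa and 1 dpa, 0.36 between 6 hpa and 3 dpa and 0.39 between 1 dpa and 3 dpa.

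Mitochondrial transcripts differed between classes as well. They made up 4.64 ± 0.40% of UMIs in regenerating and 10.5 ± 1.65% in refractory tails at 6 hpa (SD, n = 8 and 6, exact permutation p = 0.000666, adjusted p = 0.00333), and 4.53 ± 1.54% against 7.90 ± 2.20% at 1 dpa (exact permutation p = 0.00733), both between capture areas. At 3 dpa, on 1 capture area, they were 5.23 ± 0.50% and 6.31 ± 2.13% (n = 6 and 6, exact permutation p = 0.301). With each section's own 3 to 7 regions weighted equally they were 4.75 ± 0.72% and 6.14 ± 0.86% (exact permutation p = 0.0195, adjusted p = 0.0325). In region 1, led by the muscle genes myl4 and pgam2, they were 6.66 ± 0.77% and 11.1 ± 2.01% at 3 dpa (n = 4 and 5, exact permutation p = 0.0159, adjusted p = 0.0298), and 5.54% and 13.7% at 6 hpa. In refractory tails the share fell from 6 hpa to 1 dpa, on 1 capture area, from 10.5% to 7.90% (exact permutation p = 0.0433, adjusted p = 0.0590), with regions weighted equally from 9.92% to 7.36% (adjusted p = 0.0325) and in region 1 from 13.7% to 10.5% (adjusted p = 0.0232).

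Refractory tails at 1 dpa were compared with those at 6 hpa, on 1 capture area, to ask what the tail that does not regrow changes over the first day. The mitotic kinase gene cdk1.L rose to 22.7 ± 7.56 against 11.2 ± 3.86 CPM and the replication clamp gene pcna.S to 43.6 ± 14.1 against 22.7 ± 4.02 CPM (SD, n = 6 and 6). The transcription factor gene tfap2a.L fell to 11.6 ± 5.31 against 35.2 ± 12 CPM and the BMP target msx1.S to 21.0 ± 7.17 against 65.1 ± 37.9 CPM. Of 55 cell cycle genes 10 rose, and 0 with only these conditions in the fit, and the list did not pass with an estimated correlation (adjusted p = 0.247). In all, 151 genes rose and 205 fell, 62 and 90 by more than 2-fold.

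The rises were hbg2.L (5.90), fsip1.L (1.94), the chromatin regulator jarid2.L (1.32 ± 0.16, adjusted p = 1.24e-05), ddit4.L (1.17), urod.S (1.07), klf15.L (1.05) and gas6.L (1.03). They included cdk1.L (1.03 ± 0.21, adjusted p = 0.00722), rnaseh2b.L (1.01), pcna.S (0.94), sesn1.L (0.87) and ftsj3.L (0.86 ± 0.12, adjusted p = 2.67e-05). The falls were itln1.L (-2.46), des.2.L (-2.07), tlrs5.L (-1.65), slurp1l.S (-1.65), tfap2a.L (-1.64 ± 0.27, adjusted p = 0.000685), msx1.S (-1.62 ± 0.33, adjusted p = 0.00717), and lonrf1.S (-1.59 ± 0.22, adjusted p = 2.67e-05). They went on with gprc5cl1.L (-1.54), the desmosomal gene dsg2.L (-1.50), camp1.L (-1.41), cxcl14.L (-1.39) and tgm1.L (-1.39). jarid2.L, ftsj3.L and lonrf1.S passed without each section and in every alternative, and the other 21 did not. Single sections ended the call for hbg2.L (without 1 dpa section 1 or 4 or 6 hpa section 2, 4 or 5, adjusted p up to 0.159), fsip1.L (1 dpa 1, 2 or 4, 6 hpa 2, 5 or 6, 0.112), urod.S (6 hpa 4, 0.0520), klf15.L (1 dpa 2, 6 hpa 4, 0.0520), sesn1.L (1 dpa 3, 4, 5 or 6, 6 hpa 2, 4, 5 or 6, 0.119) and itln1.L (1 dpa 2, 6 hpa 5, 0.328). The same held for des.2.L (6 hpa 2, 0.0579), tlrs5.L (1 dpa 2, 6 hpa 2, 0.0692), slurp1l.S (1 dpa 2, 6 hpa 2, 0.117), gprc5cl1.L (1 dpa 1, 2 or 4, 6 hpa 4 or 5, 0.119) and camp1.L (1 dpa 1, 2, 4 or 5, 6 hpa 2, 4 or 6, 0.145).

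Cell cycle genes rose for 10 of 55 members in refractory tails (25 adjusted over the list alone), with kif11.S at 1.43 (adjusted p = 7.26e-14, and 0.247 with an estimated correlation). Epidermal genes fell for 6 of 31 (17 alone), with dsp.L at -0.75 and krt12.4.S at -2.59 (adjusted p = 3.37e-08, and 0.324 with an estimated correlation), and BMP and TGF-beta genes for 5 of 34 (9 alone), with ltbp1.S at -0.72 (adjusted p = 0.000446, and 0.434 with an estimated correlation). Camera also passed downward for myeloid markers (adjusted p = 0.000219, and 0.619 with an estimated correlation), connective tissue (0.00823 and 0.621), cytokines (0.0170 and 0.305) and apical markers (0.0328 and 0.790), and upward for spinal cord (0.00279 and 0.783), endothelium (0.0111 and 0.757) and blood (0.00949 and 0.621), where only hbg2.L passed. Single members passed in the hypoxia (ddit4.L, hk2.S -1.45), heat shock (hspa5.L -0.59), oxidative stress (sqstm1.L -0.73), p53 (sesn1.L) and goblet lists (itln1.L). The 10 risen cell cycle genes became 5, 6 and 4 without 1 dpa section 1, 2 or 4, 6 and 6 without 6 hpa section 2 or 4, and 0 with only these conditions in the fit. The 6 fallen epidermal genes became 2 and 3 without 1 dpa section 2 or 4, 11, 3 and 0 without 6 hpa section 1, 4 or 5, and 0 with library totals. The 5 fallen BMP genes became 3, 2, 3 and 3 without 1 dpa section 1, 2, 5 or 6, 2 without 6 hpa section 5, and 0 with library totals. Library totals shifted the median of all genes by 0.13 and left 78.9% of called genes risen in place of 42.4% (90 risen and 24 fallen). Counts risen and fallen were 92 and 130 without 1 dpa section 1, 75 and 79 without section 2, and 82 and 104 without section 4. They were 286 and 396 without 6 hpa section 1 and 84 and 116 without section 4, with 87 risen without section 2 and 93 fallen without section 5. With only these conditions in the fit, 4 genes rose and 4 fell, and with the outside profile subtracted 4 rose and 2 fell.

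Regenerating tails at 1 dpa were compared with those at 6 hpa on 1 capture area to ask what changes as regrowth starts. edgeR called 0 of 15163 genes (1099 at an unadjusted p under 0.05, smallest adjusted p = 0.149), DESeq2 called 2 risen and 4 fallen, and limma-voom 0 and 1. The lectin itln1.L changed by 0.47 ± 0.45 (adjusted p = 0.854), the keratin krt12.5.L by 0.49 ± 0.22 (adjusted p = 0.626), the lipoprotein gene apoc1.L by 1.27 ± 0.41 (adjusted p = 0.541) and the neuronal tubulin tubb2b.S by -0.50 ± 0.39 (adjusted p = 0.814, n = 8 and 8 sections each). As lists, apical markers (adjusted p = 7.84e-06, and 0.427 with an estimated correlation), epidermis (3.04e-05 and 0.445), goblet and ciliated genes (0.00179 and 0.305) and heat shock genes (0.00778 and 0.305) shifted upward by camera. Spinal cord genes (4.35e-10 and 0.386), hypoxia genes (0.00124 and 0.358), muscle progenitors (0.00688 and 0.580) and muscle genes (0.00949 and 0.845) shifted downward, and the muscle median of -0.38 turned to 0.20 in the sections marked by the authors. Adjusted over the list alone, 1 apical, 1 blood and 1 gut gene rose. Counts risen and fallen were 1 and 2 without 1 dpa section 5, and 0 and 1 without 1 dpa section 1, 2 or 8. With the outside profile subtracted 110 rose and 12 fell, and with the authors' marked sections alone 184 genes rose and 319 fell.

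The change from 6 hpa to 1 dpa was then compared between classes, which addresses whether the first day runs differently in tails that regrow. A difference between capture areas of the same fold at both times cancels here, while RNA spread need not. The epidermal regulator tfap2a.L went from 37.2 ± 9.32 to 42.1 ± 14.3 CPM in regenerating tails (SD, n = 8 and 8) and from 35.2 to 11.6 CPM in refractory tails (n = 6 and 6). The BMP target msx1.S went from 68.0 ± 19.3 to 85.7 ± 24.1 CPM and from 65.1 to 21.0 CPM. jarid2.L went the other way, from 18.6 ± 4.95 to 15 ± 2.46 CPM and from 30.2 to 75.7 CPM. The change was higher in regenerating tails for 174 genes and lower for 69, 125 and 38 of them by more than 2-fold.

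Higher changes were those of tll2l.L (4.49), itln1.L (2.93), krt12.4.S (2.91), apoc1.L (2.59), the cadherin cdh26.S (2.20 ± 0.43, adjusted p = 0.00778), tmprss2.2.L (1.98) and msx1.S (1.95 ± 0.43, adjusted p = 0.0213). Next were ptgr1.3.L (1.88), lonrf1.S (1.86 ± 0.28, adjusted p = 0.000227), lypd2.L (1.84), tfap2a.L (1.81 ± 0.34, adjusted p = 0.00656) and the fibrillin fbn2.L (1.76). Lower changes were those of the myosin gene myl3.L (-3.69), jarid2.L (-1.63 ± 0.23, adjusted p = 0.000148), ddit4.S (-1.59), sh3glb2.S (-1.53), klf15.L (-1.50) and urod.S (-1.41). Also lower were ctbp1.L (-1.24), the mitotic motor kif11.S (-1.19), ankrd10.L (-1.05), psma5.L (-1.01), dhx9.L (-0.99) and nup88.L (-0.93). cdh26.S, lonrf1.S, tfap2a.L, jarid2.L, klf15.L and urod.S passed without each section, and lonrf1.S also in every alternative (largest adjusted p = 0.0416). jarid2.L was lost with regions weighted equally alone (0.140, range 6.16e-08 to 0.140). All of the other 18 lost the call without refractory 6 hpa section 5. Without refractory 1 dpa section 2 the call was lost for 14 of them, all but msx1.S, myl3.L, ddit4.S and dhx9.L, and without refractory 1 dpa section 4 for 14, all but msx1.S, myl3.L, psma5.L and nup88.L. Without regenerating 1 dpa section 4 it was lost for 12 of them and without section 6 for 11, and each further section of either class ended it for 8 or fewer, with krt12.4.S reaching the largest adjusted p of these genes (0.320).

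Epidermal genes led the difference in time course, with 6 of 31 members higher (19 adjusted over the list alone), among them cldn4.L (1.73) and krt12.4.S (adjusted p = 4.92e-11, and 0.253 with an estimated correlation). BMP and TGF-beta genes were higher for 3 of 34 (12 higher and 1 lower alone), with msx1.S and id2.S (1.05) (adjusted p = 0.000467, and 0.434 with an estimated correlation). Apical markers had 0 members past the threshold in edgeR over all genes and 8 adjusted over the list alone, with bambi.L at 1.89 (adjusted p = 9.12e-05, and 0.455 with an estimated correlation). Cell cycle genes were lower for 1 of 55, kif11.S (14 alone, adjusted p = 2.83e-08, and 0.347 with an estimated correlation), and in refractory tails alone they rose for 10 of 55. Spinal cord genes shifted downward (2.83e-08 and 0.445), as did endothelium (0.00797 and 0.730) and hypoxia genes (0.0260 and 0.580, ddit4.S). Myeloid markers (0.000380 and 0.621), cytokines (0.0104 and 0.253), immediate early genes (0.0466 and 0.83) and heat shock genes (0.00778 and 0.305, hspa5.L 0.77) shifted upward. The heat shock median of 0.21 turned to -0.01 with regions weighted equally, also without TMM. Single members passed in the goblet (itln1.L), connective tissue (fbn2.L), oxidative stress (sqstm1.L 0.77) and gut lists (apoc1.L), and metalloproteases had a median of -0.25 and a mean of 0.06. The 6 higher epidermal genes became 2 and 1 without refractory 1 dpa section 2 or 4, 12, 3 and 0 without refractory 6 hpa section 1, 4 or 5, and 1, 10, 1 and 2 without regenerating 1 dpa section 4, 5, 6 or 8. They became 2, 3 and 1 without regenerating 6 hpa section 2, 6 or 7. The 3 higher BMP genes became 1 without refractory 1 dpa section 2 or 4 or regenerating 1 dpa section 4, 6 or 8, 0 without refractory 6 hpa section 5, and 7 and 6 without refractory 6 hpa section 1 or 3.

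The interaction counts depended on scaling and on single sections of each condition. Library totals shifted the median of all genes by -0.19 and called 2 genes higher and 10 lower, 16.7% higher in place of 71.6%, and limma-voom gave 107 higher, 52.5%. Higher genes in the other alternatives ran from 2 (regions weighted equally, also without TMM) to 272 (DESeq2). Higher and lower genes numbered 108 and 43 without refractory 1 dpa section 1, 50 and 27 without section 2, and 53 and 24 without section 4. They numbered 356 and 200 without refractory 6 hpa section 1, 108 and 43 without section 4, and 19 and 15 without section 5. Without regenerating 1 dpa section 4, 6 or 8 they were 59 and 31, 58 and 38, and 71 and 36, and 125 genes were lower without section 5. Without regenerating 6 hpa section 2, 6 or 7 they were 95 and 42, 95 and 40, and 81 and 39, and 107 genes were higher without section 8.

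Regions inside the tails addressed where the class differences lie. Region 1 was led by myl4, pgam2 and myoz1, region 2 by krt62, lum and postn, region 3 by otos, eln2 and epyc, and region 4 by slc45a2, pmel and dct. Region 5 was led by mmp13l, cxcl8, muc1 and ptgs2, region 6 by lmo2, stab2 and aplnr, region 7 by nefm, syp and tac1, and region 8 by pltp, tll2l, bhlha9, mmp3 and frem3. Region 5 held 51, 37 and 4 regenerating and 167, 123 and 262 refractory spots at 6 hpa, 1 dpa and 3 dpa. Region 8 held 66, 208 and 54 regenerating and 3, 3 and 1 refractory spots. Their shares were untested between classes, as their leading genes differed, which a shifted share can cause. So 0 of 17 shares passing exact permutation tests (2 at unadjusted p under 0.05) says little, and the smallest adjusted p was 0.202. It was that of region 8 in regenerating tails over time (21.8 ± 16.7% of spots at 1 dpa and 5.5 ± 4.51% at 6 hpa, n = 8 and 8, exact permutation p = 0.0154) and of region 6 at 3 dpa (6.58 ± 3.65% of spots in regenerating and 1.42 ± 2.24% in refractory tails, n = 6 and 6, exact permutation p = 0.0238). Inside region 1, 121 genes were higher and 125 lower in regenerating tails at 3 dpa, and inside region 3 it was 99 and 89. Inside region 4 it was 36 and 148, and inside region 7 16 and 118 (4 sections of each class). With at least 10 spots per section only region 3 could be compared at 3 dpa (74 and 71).

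Co-localisation asked whether injury genes lay with particular tissues in the same spots. Of 144 pairs of lists and conditions, 0 passed the exact sign-flip test (53 at an unadjusted p under 0.05, smallest adjusted p = 0.0882), and with spots thinned to 1000 UMIs also 0 (40 unadjusted). The smallest exact p that 8 sections allow is 0.00781, and that of 6 sections 0.0313, so pairs in conditions with 6 sections could hardly pass. Metalloprotease and epidermal genes correlated in all 6 refractory sections at each time, with mean rho of 0.78 ± 0.08 at 6 hpa, 0.74 ± 0.12 at 1 dpa and 0.57 ± 0.11 at 3 dpa (SD, n = 6), against 0.00, 0.04 and 0.21 in regenerating sections (n = 8, 8 and 6). The classes differed by exact permutation in a family of 72 tests chosen after the data were seen (exact permutation p = 0.000666, 0.000666 and 0.00433, adjusted p = 0.0120, 0.0120 and 0.0312), and at 3 dpa both classes lay on 1 capture area. The members behind the list differed, since mmp1.S and mmp8.S made up 40.2% and 33.2% of its UMIs in refractory tails at 6 hpa and mmp1.S and mmp7.L 25.4% and 14.4% in regenerating tails. Between capture areas at 6 hpa, metalloproteases lay with myeloid markers in 8 of 8 regenerating sections (rho 0.54 against 0.11, exact permutation adjusted p = 0.0120), and with spots thinned to 1000 UMIs the regenerating value was 0.19. The classes did not differ past the threshold for this pair at 1 dpa (0.44 against 0.25, exact permutation p = 0.159) or, on 1 capture area, at 3 dpa (0.11 against 0.20, exact permutation p = 0.390). Immediate early genes correlated with epidermal genes more in refractory than in regenerating tails at 6 hpa (0.71 against 0.06, adjusted p = 0.0120) and 1 dpa (0.58 against 0.21, adjusted p = 0.0480), between capture areas. At 3 dpa, on 1 capture area, it was 0.22 against 0.20 (exact permutation p = 0.913). Further pairs past the threshold between capture areas, refractory against regenerating, were metalloproteases with connective tissue (0.41 against -0.04, adjusted p = 0.0192) and with spinal cord genes (-0.30 against 0.06, adjusted p = 0.0240) at 1 dpa, and cytokines with epidermal genes at 6 hpa (0.39 against 0.03, adjusted p = 0.0223) and with muscle genes at 1 dpa (-0.49 against -0.18, adjusted p = 0.0266). On 1 capture area, apical with myeloid markers at 3 dpa passed as well (0.11 against -0.13, exact permutation p = 0.00216, adjusted p = 0.0223).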

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

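The tests of section depth, of RNA spread and of mitochondrial transcripts alone, and those of the sections marked by the authors, were chosen after the results they concern had been seen. Muscle, ribosomal and cell cycle shares set regenerating section 1 of 3 dpa apart, and epidermal and metalloprotease shares set refractory section 5 of 6 hpa apart. In 236 groups of sections, 35 single sections stood far from the others of their condition. Chance gives about 1 in 20 groups, so some of these flags are chance, and none of them was removed from the comparisons.

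At 3 dpa, regenerating section 1 had the lowest percent of UMIs from cytokines (0.0313), Wnt and FGF genes (0.0682) and cell cycle genes (0.192), and was highest for muscle (3.81), muscle progenitors (0.0145), ribosomal proteins (27.4) and oxidative phosphorylation genes (3.71), and with 642 CPM of ocm4.7.L. Without it the call of ocm4.7.L was lost, and 107 ribosomal genes were lower in place of 44. Regenerating section 4 stood apart for notochord genes (0.793%). Among refractory sections of 3 dpa, section 1 was lowest for Wnt and FGF genes (0.0658%) and highest for cytl1.L (148 CPM), section 4 stood apart for pigment genes (0.0923%), and section 6 for cat2.L (16.4 CPM).

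At 6 hpa, refractory section 5 stood apart for metalloproteases (0.859%), epidermis (1.73%), krt12.4.S (72.2 CPM), itln1.L (215 CPM) and ddit4.L (23.1 CPM). Section 3 was lowest for BMP and TGF-beta genes (0.137%), section 4 apart for connective tissue (2.07%), section 6 for blood genes (0.919%) and section 2 for tlrs5.L (95.2 CPM). Among regenerating sections of 6 hpa, section 6 was highest for Wnt and FGF genes (0.0940%) and section 3 had the most UMIs (2574995).

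At 1 dpa, refractory section 5 had 55 spots, against 128 in the next, and stood apart for muscle progenitors (0.0302%) and endothelium (0.0127%). Refractory section 1 had 147 CPM of hbg2.L, and section 3 had 16.1 CPM of itln1.L and 34.6 CPM of tlrs5.L. Regenerating section 1 had 5843 CPM of itln1.L, 0.646% of UMIs from goblet and ciliated cell genes and 7.93% from mitochondrial transcripts. Regenerating section 6 was highest for apical markers (0.124%) and section 4 for cnfn.1.S (1.66 CPM).

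The change from 6 hpa to 1 dpa differed between the classes for 174 genes upward and 69 downward in regenerating tails, tested as an interaction. With library totals it was 2 and 10, and the median of all genes shifted by -0.19. By camera at the preset correlation, epidermis (median log2 0.90, camera adjusted p = 4.92e-11, 0.253 with an estimated correlation), apical markers (0.82, 9.12e-05 and 0.455), myeloid markers (0.80, 0.000380 and 0.621), BMP and TGF-beta genes (0.43, 0.000467 and 0.434), immediate early genes (0.32, 0.0466 and 0.83), cytokines (0.29, 0.0104 and 0.253) and heat shock genes (0.21, 0.00778 and 0.305) shifted upward. Spinal cord (-1.21, 2.83e-08 and 0.445), endothelium (-0.63, 0.00797 and 0.730), cell cycle (-0.56, 2.83e-08 and 0.347) and hypoxia genes (-0.27, 0.0260 and 0.580) shifted downward. None passed with an estimated correlation, the last value of each, and members past the threshold were 6 of 31 epidermal, 3 of 34 BMP, 1 of 31 heat shock, 1 of 55 cell cycle and 1 of 34 hypoxia genes and 0 in the other lists. Of 100 splits of the sections, 1 gave as many called genes, the real one (243, highest other 189). This makes chance unlikely at 1 in 100 but does not exclude it. The counts ran from 19 to 356 upward and from 15 to 200 downward between left-out sections.

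Spots outside tissue, which were used only for the subtracted profile, held a median of 2516, 1992 and 6764 UMIs on the first, the second and the third capture area, 35.4%, 38.0% and 41.5% of all UMIs. The share was highest on the area of regenerating 6 hpa and 1 dpa tails, and with this profile subtracted itln1.L and krt12.4.S no longer passed at 6 hpa.

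More genes differed between the classes at 6 hpa (6633) and 1 dpa (6765) than at 3 dpa (854), where both classes shared a capture area. Of the genes called in 1 direction at both early times, 69.5% had that direction at 3 dpa. Splits of the 3 dpa sections gave up to 69.3% (median 50.7%), too close to decide whether the capture area is the whole cause. Section depth as the cause was argued against, since the count at 6 hpa was 8.39 times that at 3 dpa with all sections thinned (7.77 before). RNA spread stays open, because the ratio of 18.6 after subtraction rests on an assumed profile. Divergence of young and old tails in the first day may contribute. It cannot be told from the capture area or, without uncut tails, earlier differences.

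Mitochondrial transcripts took a larger share in refractory tails at 6 hpa, between capture areas. The tables argue against a different mix of muscle and other regions as the cause, since 93.1% of the difference was left with regions weighted equally. Loss of other RNA from damaged cells, with mitochondrial transcripts alone retained, stays open. Of 132 nuclear oxidative phosphorylation genes 99 were lower in regenerating tails too, but 54 without refractory section 3 and 64 with the outside profile subtracted. The list did not pass with an estimated correlation (adjusted p = 0.790). These genes took 6.29% of UMIs in region 1 and 2.41% to 3.58% in the others. Muscle genes took 4.14% in refractory and 2.59% in regenerating sections, so tissue mix was not excluded as part of it. The capture area, which coincides with class here, stays open, and age was not tested.

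The authors' marked sections, 4 per time, gave 503 genes between 1 dpa and 6 hpa in regenerating tails, where all 16 sections gave 0. Among 35 splits of the marked sections 2 gave as many (highest other 739), so chance was not excluded. Among 100 random choices of 4 sections per time 2 gave as many (highest other 546), so such a count was not usual for any 4 sections. Genes such as ctgfl.L (-4.40), cadm3.L (-2.99), the neurofilament nefm.S (-2.97) and tnf.S (2.43) were chosen after their values were seen, and the position of the sections along the tail was not tested.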

How the results depend on the processing

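The authors' marked sections, touching pieces as 1 section, the outside profile, list counts under alternatives and the co-localisation test between classes were chosen after seeing the data. Between left-out sections the counts at 6 hpa and 1 dpa moved little, and those of refractory tails over time and of the interaction moved most. Of the named genes' fold changes, 5502 values under alternatives kept direction and call, 621 kept direction and lost the call, 9 gained it and 7 reversed, and without single sections 6739 were kept, 377 lost the call, 10 gained it and none reversed. Co-localisation tests within a condition were not read for stability, since 6 sections allow no p under 0.0313 and fewer sections none under 0.05. Beyond fewer sections or UMIs, no cause was tested. Counts below are genes higher, then lower.

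At 3 dpa (345 and 509) library totals gave 580 and 270, regions weighted equally 544 and 238, touching pieces as 1 section 113 and 172 (fewer sections), and the outside profile subtracted 68 and 86. Of the 854 genes, DESeq2 called 824 (1078 in all), library totals 585 (850), regions weighted equally 435 (782), touching pieces 281 (285) and the outside profile 153 (154). Without single sections the counts ran from 232 to 372 and from 307 to 660.

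At 6 hpa (3140 and 3493) regions weighted equally gave 2165 lower, and the outside profile subtracted 1095 and 1770. Without single sections they ran from 2860 to 3198 and from 3180 to 3567. At 1 dpa (3237 and 3528) regions weighted equally gave 2241 lower, and the outside profile subtracted 814 and 816, with 2972 to 3241 and 3189 to 3526 without single sections. Reversed with homeologs summed, where the value is that of both copies together, were lep.S (-0.78), mpo.S (-0.50) and ndufa7.S (-0.30) at 6 hpa and matn4.S (-0.49), col3a1.L (0.053) and ndufa7.S (-0.38) at 1 dpa. prdx1.L reversed to -0.18 at 6 hpa with the outside profile subtracted.

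For regenerating tails over time (0 and 0) DESeq2 gave 2 and 4, limma-voom 1 lower, regions weighted equally 1 lower, the outside profile subtracted 110 and 12, and the marked sections 184 and 319. Without single sections they ran from 0 to 1 and from 0 to 2.

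For refractory tails over time (151 and 205) library totals gave 90 and 24 and no filter 90 and 64. Only these conditions in the fit gave 4 and 4 (same sections), so most calls needed the others. Thinning gave 92 and 123 (fewer UMIs), regions weighted equally 41 lower and the outside profile subtracted 4 and 2. Without single sections they ran from 75 to 286 and from 79 to 396. Marked sections hold none of refractory 6 hpa, so this comparison, that at 6 hpa and the interaction had no value there.

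For the interaction (174 and 69) DESeq2 gave 272 and 120, limma-voom 107 higher, library totals 2 and 10, regions weighted equally 2 and 11, no filter 18 and 19, only these conditions 65 and 24, all tissue spots 94 and 44, thinning 15 and 7, touching pieces 22 and 11, and the outside profile subtracted 22 and 6. Without single sections they ran from 19 to 356 and from 15 to 200.

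Of 150 gene list tests camera called 61 with the preset correlation, 3 with an estimated correlation and fry 40. Library totals also brought camera past the threshold for muscle and oxidative phosphorylation in refractory tails over time, for muscle progenitors, spinal cord, connective tissue and ribosomal genes at 1 dpa, and for goblet, connective tissue and oxidative phosphorylation genes in the interaction. With at least 10 spots per section whole regions dropped out of the comparisons inside regions. At 3 dpa region 3 alone was left with 145 calls (74 higher and 71 lower, 99 and 89 with 5 spots), and at 1 dpa 4128 calls came from regions 1 (1167 and 1224, before 1025 and 1132), 3 (517 and 451, before 555 and 463) and 6 (404 and 365, before 405 and 368). Named genes kept without each section numbered 16 of 24 at 3 dpa, 24 at 6 hpa, 24 at 1 dpa, 13 for refractory tails over time and 6 for the interaction. Those kept in every alternative too numbered 9, 18, 22, 3 and 1.

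No paired analysis was possible because the labels give no numbers that pair sections. Small changes were often missed: of simulated 1.5-fold changes 16.4% were found at 3 dpa and 2.99% in the interaction.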

Other observations

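The tests of co-localisation between classes and the reading of genes shared by all times were chosen after the results had been seen. krt12.4.S was higher in regenerating tails at 6 hpa, 1 dpa and 3 dpa (log2 5.58, 8.49 and 2.81), itln1.L likewise (5.03, 7.96 and 2.57), and thdl17.L (-7.85, -7.60 and -5.18) and muc1.S (-6.49 at 6 hpa, -2.61 at 3 dpa) were lower, between capture areas at both early times. With the outside profile subtracted krt12.4.S (adjusted p = 0.101) and itln1.L (0.938) did not pass at 6 hpa, and itln1.L did not at 3 dpa with touching pieces as 1 section (0.0539). Of 2087 genes higher at both early times, 198 were also higher at 3 dpa, and of 2450 lower, 216 were also lower.

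Cell cycle genes took 0.216%, 0.219% and 0.306% of UMIs (section means) in regenerating and 0.0690%, 0.106% and 0.223% in refractory tails at 6 hpa, 1 dpa and 3 dpa. Immediate early genes took 0.151%, 0.155% and 0.172% against 0.503%, 0.483% and 0.244%. Metalloproteases, with members split both ways early, took 0.133%, 0.131% and 0.133% against 0.384% (40.2% of it mmp1.S, 33.2% mmp8.S), 0.338% and 0.209%. Each class difference was smaller at 3 dpa than earlier, between capture areas, and its change was not tested.

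For each comparison other splits of the same sections were counted. At 3 dpa only the real one of 100 splits gave as many genes (854, highest other 544). The same held at 6 hpa (6633, highest other 3380) and 1 dpa (6765, highest other 4692). Chance is unlikely at 1 in 100 but not excluded. For refractory tails over time 4 of 100 splits gave as many (356, highest other 2537), a share under 0.05, but a split with several times the real count points to a structure of these sections other than time. For regenerating tails over time all 100 splits gave at least the 0 genes called (highest other 63), an outcome fixed by the count of 0, so the splits decide nothing there.

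Metalloprotease and epidermal genes shared spots in refractory tails at each time (mean rho 0.78, 0.74 and 0.57) and less in regenerating tails (0.00, 0.04 and 0.21). Region 5, led by mmp13l, cxcl8, muc1 and ptgs2, held 262 refractory and 4 regenerating spots at 3 dpa. The exact sign-flip test on 6 sections was at its floor (p = 0.0313, adjusted p = 0.0882) and decided nothing here, and the tests between classes, chosen after the data were seen, passed (adjusted p = 0.0312 at 3 dpa, on 1 capture area). RNA that spread from neighbouring spots was not excluded for these correlations.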
